A study of Danio rerio with 4 samples.

How the data were processed

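Whole retinae of wild-type zebrafish aged 10 months were profiled by RNA sequencing in 4 groups: uninjured, 12 hours post injury (12 hpi), 4 days post injury (4 dpi), and 4 days post injury with valproic acid (4 dpi + VPA), in which the fish were kept in 100 µM VPA for 4 days, per the labels' protocols. Valproic acid is an inhibitor of histone deacetylases. The labels give 1 GEO sample per group, and the series' design text speaks of duplicate samples. How the retina was injured is not given in the sources used here.

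The authors deposited 6 tables, a higher and a lower one for each of the 3 injured groups against the uninjured group. Reads were processed with Bowtie2 2.2.2, TopHat2 2.1.0 and Cufflinks 2.2.1 on the genome build GRCz10, per the submitters' processing notes. Per the file headers, each entry holds an FPKM value (fragments scaled to transcript length and to the mapped fragments of the group) for uninjured retina and for the injured group, which the authors had computed as 1 value per group. The log2 fold change, the test statistic (a score), the p-value and the q-value were computed by the authors too, per the file headers. The deposited log2 fold change equalled the log2 of the ratio of the FPKM values with no pseudocount and was infinite where a group was at 0. The deposited tables were filtered: every listed entry had a p-value of at most 0.05 and an FPKM above 1 in the higher group, as read from the values, and the number of genes tested by the authors is not given in the sources used here. The q-values of the authors were kept as deposited and were not recomputed. The 4 dpi tables held 1466 entries for genes, while the tables for 12 hpi held 619 entries and those for 4 dpi + VPA held 1069 entries for single transcripts. Of the transcripts listed at 12 hpi and at 4 dpi + VPA, 257 were shared, and their uninjured FPKM values were identical.

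Groups were taken from the labels. With 1 pooled value per group there were no replicate values, so no test of differential expression was run and no replicate check of any difference was possible. Sequencing depth per library is unknown from the tables used here. The authors' fold changes, p-values and q-values were copied and described. A standard error of a log2 fold change was derived as the deposited log2 fold change divided by the authors' test statistic. The authors' p-values were a median of 1.34 to 1.40 times those of a normal distribution at the same statistic, and for single genes with large changes far more, so that this standard error understates the uncertainty of such genes. Its median over shared features lay between 0.829 and 0.881 for the comparisons taken in pairs. Genes were counted as distinct gene names, and a gene with entries in both directions was counted in neither. Coordinates are those of the deposited tables on GRCz10.

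Before the data were examined, 30 gene lists holding 1462 different genes were written down. They covered regeneration-associated factors, the cell cycle, rod, cone and shared photoreceptor genes, bipolar, amacrine and horizontal, and retinal ganglion cells, Müller glia, pigment epithelium, macrophages and microglia, neutrophils, inflammatory signalling, the interferon response, immediate early and AP-1 genes, heat shock and chaperones, the Notch pathway, the Wnt, Hedgehog and TGF-beta pathways, extracellular matrix and adhesion, HDAC and histone modifiers, cholesterol and fatty acid synthesis, the circadian clock, apoptosis, ribosomal proteins, mitochondrially encoded genes, red blood cells, lens, cornea and skin, muscle, endothelial cells and pericytes, and oligodendrocytes and optic nerve. For each list and comparison, the members listed higher and lower were counted, and the median of log2((FPKM + 0.1)/(uninjured FPKM + 0.1)) over the listed members was computed, with the entry of highest mean FPKM for each gene. For lists with at least 5 listed members, the median's percentile among 10000 random lists of the same size was given. Random lists were drawn with seed 20240501 from the listed genes of that comparison, within 10 bins of mean log2 FPKM. The genes drawn from included the members of the list itself and genes of both directions. A list with all members higher can therefore reach a high percentile without larger changes than other genes listed higher. A list that fills most of a bin is compared largely with itself. Percentiles below 2.5 or above 97.5 are called outside the limits, as a description of these libraries and not as a test. A list member that was not listed had either not passed the authors' filter or not been measured.

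The genes named in the text followed a rule fixed at the same time. In each comparison these were the 10 highest and the 10 lowest finite log2 fold changes of the authors with an FPKM of at least 5 in the higher group and an established symbol, up to 4 members of each list with the largest change and an FPKM of at least 1, and every listed regeneration-associated factor. For 4 dpi + VPA against 4 dpi the rule named the 10 highest and the 10 lowest ratios and the listed members of the regeneration, cell cycle and HDAC lists. The genes the authors marked significant were added later. Any other gene is named as chosen after its values were seen, and the text gives a part of the genes under the rule. Some genes under the rule are not reported here.

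Genes listed in more than 1 comparison were matched by name. Because all comparisons shared the uninjured control, 1000000 pairs of unchanged comparisons with a shared control were simulated with equal noise in every group. The simulated share of entries listed in both and the share with the same sign were thus the same for every pair of comparisons. Only the simulated covariance of log2 fold changes about 0 was scaled by the standard errors implied by the authors' scores. The simulated values were set beside the observed values. These observed shares were counted over table entries, and the covariance over shared entries with an FPKM of at least 0.1 in every group, a test statistic above 0.5 in size and an uninjured FPKM equal within 10%. The ratios of 4 dpi + VPA to 4 dpi exist only for genes that passed the authors' filter in both, so for each list the lowest possible median and lower quartile over all members higher at 4 dpi were also computed, with members without a ratio placed lowest. The overlap of independent lists was not computed because the number of genes tested was not known, and the control could not be split. To set 4 dpi + VPA beside 4 dpi, log2((FPKM 4 dpi + VPA + 0.1)/(FPKM 4 dpi + 0.1)) was computed for genes listed in both, matched here by gene identifier, whose uninjured FPKM was equal within 10% in both tables. Genes with 1 annotated transcript, for which gene and transcript values are the same quantity, served as a check of the gene-level against the transcript-level tables.

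The calculation of list percentiles was tested on simulated lists of 15 genes. Among the 599 genes at 12 hpi, 5.5% of 200 lists with no shift fell outside the limits, as did 37.5%, 85.0% and 92.5% of 40 lists shifted by 1, 2 and 3 log2 units. Among the 1434 genes at 4 dpi these shares were 5.0%, 70.0%, 75.0% and 77.5%, and among the 1036 genes at 4 dpi + VPA they were 7.0%, 47.5%, 75.0% and 72.5%. The simulated lists were drawn at random from genes of both directions. The shares with no shift therefore do not tell how often a list with all members higher falls outside the limits through direction alone. The alternatives tried were a q limit of 0.01 or 0.1, a fold change of at least 4, an FPKM of at least 1 in a group, an FPKM of at least 0.01 in both groups, counting of entries, genes with 1 annotated transcript, pseudocounts of 1 and 0.01, summed entries or the entry with the largest change per gene, matching by gene identifier, and an uninjured tolerance of 1% or none. Gene names came from the deposited tables, and 557, 1325 and 968 gene identifiers of the 12 hpi, 4 dpi and 4 dpi + VPA tables were found in a table of current symbols. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.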

Results

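Whole-retina transcriptomes were compared between uninjured zebrafish and fish at 12 hpi, at 4 dpi, and at 4 dpi with valproic acid (VPA), an inhibitor of histone deacetylases. Each group was represented by 1 GEO sample and by 1 pooled FPKM value per gene or transcript, computed by the authors, so no difference has a replicate check. Against uninjured retina, the authors' deposited tables listed 381 genes higher and 213 lower at 12 hpi, 865 higher and 569 lower at 4 dpi, and 595 higher and 439 lower at 4 dpi + VPA, all at an unadjusted p of at most 0.05. A further 5 genes at 12 hpi and 2 genes at 4 dpi + VPA had transcripts in both directions. The authors had marked 40 higher and 5 lower genes significant, all in the 4 dpi tables. The smallest p, 5e-05, stood beside q = 0.0421 in the gene-level 4 dpi tables and q = 0.0717 in the transcript-level tables of 12 hpi and 4 dpi + VPA in the authors' deposited tables, so the numbers marked follow the table level and cannot be compared between groups.

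In order to describe the early response to injury, retinae at 12 hpi were compared with uninjured retinae. Transcription factors and signalling genes of the injury response were listed higher. *atf3*, a stress-induced transcription factor, was at 0.952 FPKM in uninjured retina and 81.8 FPKM at 12 hpi, a log2 fold change of 6.42 (SE 0.99, p = 5e-05, q = 0.0717) in the authors' deposited table. *socs3b*, a feedback inhibitor of cytokine signalling, was at 2.39 and 87.4 FPKM, with a log2 fold change of 5.19 (SE 0.90, p = 5e-05, q = 0.0717) in the authors' deposited table. *mmp9*, a matrix-degrading protease, was at 0.363 and 47.8 FPKM, with a log2 fold change of 7.04 (SE 1.15, p = 0.0068, q = 0.997) in the authors' deposited table, where this p is larger than the SE would give. Photoreceptor genes were among those listed lower, and *grk1b*, an opsin kinase, was at 53.8 FPKM in uninjured retina and 4.45 FPKM at 12 hpi. On GRCz10, *atf3* lies on chromosome 20 from 37891753 to 37897858, *socs3b* on chromosome 12 from 34157075 to 34176402 and *mmp9* on chromosome 8 from 24260272 to 24274708.

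All 15 listed members of the immediate early and AP-1 list were higher, with a median log2 change of 3.41 at percentile 100.0 of the random lists. *fosab*, a subunit of the AP-1 transcription factor, was at 1.90 and 77.3 FPKM, and *cebpb*, a transcription factor of the acute phase response, was at 0.861 and 26.3 FPKM. Of the inflammatory signalling list, 19 genes were higher, 0 were lower and *il6st*, the shared receptor subunit of the interleukin 6 family, had transcripts in both directions, and the median of the list was 3.38 (percentile 100.0). The chemokine gene *ccl34a.4* was listed at 0 in uninjured retina and at 49.2 FPKM at 12 hpi. The complement gene *cfb* was at 0 and 1.39 FPKM. Of 60 regeneration-associated factors 6 were listed, all higher (median 4.34, percentile 99.9). Of these 6, *hbegfa* and *socs3b* are also on the immediate early list and *socs3b* and *stat3* on the inflammatory list, so the lists are not separate results. Among the 6, the cytokine receptor-like gene *crlf1a* was at 0.659 and 43.6 FPKM, the Myc family members *mycb* and *mych* were at 5.25 and 59.6 FPKM and at 0.579 and 26.0 FPKM, the growth factor gene *hbegfa* was at 0.621 and 8.33 FPKM, and *stat3*, which acts downstream of interleukin 6 family cytokines, was at 7.84 and 79.5 FPKM. The neutrophil list of 22 genes had 5 members higher and 1 lower (median 4.95, percentile 99.7). Its median was 2.76 at a pseudocount of 1 and 5.83 (percentile 95.88) at 0.01, and *lect2l* was listed at 0 and 6.44 FPKM. Of the 5 higher, *mmp9* and *timp2b* are also on the inflammatory list and on the extracellular matrix list, so these lists are not separate results either. The macrophage and microglia list had 4 higher, among them *cd63* at 10.1 and 72.7 FPKM and *rac2* at 0.698 and 7.38 FPKM, and 1 lower (median 2.84, percentile 69.8).

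All 10 listed heat shock and chaperone genes were higher (median 2.57, percentile 93.7), including *hspb11* at 1.07 and 87.3 FPKM, *hsp70l* at 4.58 and 61.5 FPKM and *cryabb*, a small heat shock protein gene, at 0.688 and 13.2 FPKM. The 9 listed extracellular matrix and adhesion genes were higher (median 2.87, percentile 90.8), and *timp2b*, an inhibitor of matrix proteases, was at 3.33 and 84.4 FPKM in its more abundant transcript. Ganglion cell and Müller glia genes were listed in both directions. *gap43*, a growth cone protein gene, was at 3.89 and 36.5 FPKM, *klf6a* was at 4.64 and 25.4 FPKM, and the RNA-binding protein gene *rbpms2b*, a ganglion cell marker, was at 36.2 and 9.19 FPKM, so that the ganglion cell list had 3 members higher and 1 lower. The Müller glia list had 2 higher and 1 lower, with the glutamate transporter gene *slc1a2b* at 66.1 and 16.0 FPKM and the fatty acid binding protein gene *fabp11a* at 1.54 and 93.6 FPKM.

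The few listed rod, cone and shared photoreceptor genes (3 of 28, 1 of 42 and 4 of 42) were mostly lower at 12 hpi, an exception being *nr2e3*, a photoreceptor nuclear receptor, at 11.9 and 72.3 FPKM. The rod list had 1 member higher and 2 lower, among them the recoverin gene *rcvrna* at 237 and 63.7 FPKM, and the cone list had *guca1e*, a guanylate cyclase activator, at 40.6 and 3.45 FPKM. The shared photoreceptor list had 3 lower, including *fscn2a* at 30.8 and 9.97 FPKM, and *impg2b* had transcripts in both directions. *trpm1b*, a cation channel of bipolar and pigment cells, was the 1 member listed for the bipolar list and for the pigment epithelium list, at 36.0 and 12.1 FPKM. In the clock list, 4 genes were higher and 5 lower (median -1.97, percentile 1.3). The nuclear receptor gene *rorcb* was at 60.4 and 7.18 FPKM, while *nr1d4a* was at 1.28 and 18.1 FPKM and *nr1d4b* at 1.45 and 21.0 FPKM. Without entries under 0.01 FPKM the median of the clock list was -0.287, at percentile 15.93. The 3 listed genes of cholesterol and fatty acid synthesis were lower, among them *srebf1*, a transcription factor of lipid synthesis, at 54.6 and 17.2 FPKM and the squalene synthase gene *fdft1* at 26.6 and 6.09 FPKM. The Notch list had *hey1*, a Notch target gene, at 7.10 and 1.01 FPKM, and the Wnt, Hedgehog and TGF-beta list had 1 member higher. The interferon list had *cd40* and *irf9* higher, with *cd40* at 5.66 and 31.4 FPKM, and the ribosomal protein list had a transcript of *rps28* higher.

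Genes of the lists for lens, cornea and skin and for red blood cells were also listed higher at 12 hpi. All 16 listed members of the lens, cornea and skin list were higher (median 5.80, percentile 100.0), with a median of 3.85 at a pseudocount of 1 and 8.42 at 0.01, and the crystallin genes *crygm3*, *crygs4* and *cryaa* were at 0 in uninjured retina and at 121, 71.2 and 50.0 FPKM. The 4 listed red blood cell genes were higher, with the beta globin gene *ba1* at 53.7 and 349.6 FPKM. The lists for the cell cycle, amacrine and horizontal cells, HDAC and histone modifiers, apoptosis, mitochondrially encoded genes, muscle, endothelial cells and pericytes, and oligodendrocytes and optic nerve had 0 listed members. At 12 hpi the lowest q was 0.0717, shared by 24 transcripts at p = 5e-05, with a median q of 0.997 in the authors' deposited table. The authors marked 0 transcripts significant there, although the same p was marked in the gene-level 4 dpi tables. Of the 24 transcripts at the lowest q, 8 were of the lens, cornea and skin list. Among the genes of the named-gene rule, the highest fold changes included *ss18*, *irf9*, *rps28*, *aurkaip1*, *smim13*, *sf3a3* and *ubfd1*, each for a transcript below 0.01 FPKM in uninjured retina.

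**Figure D1:**
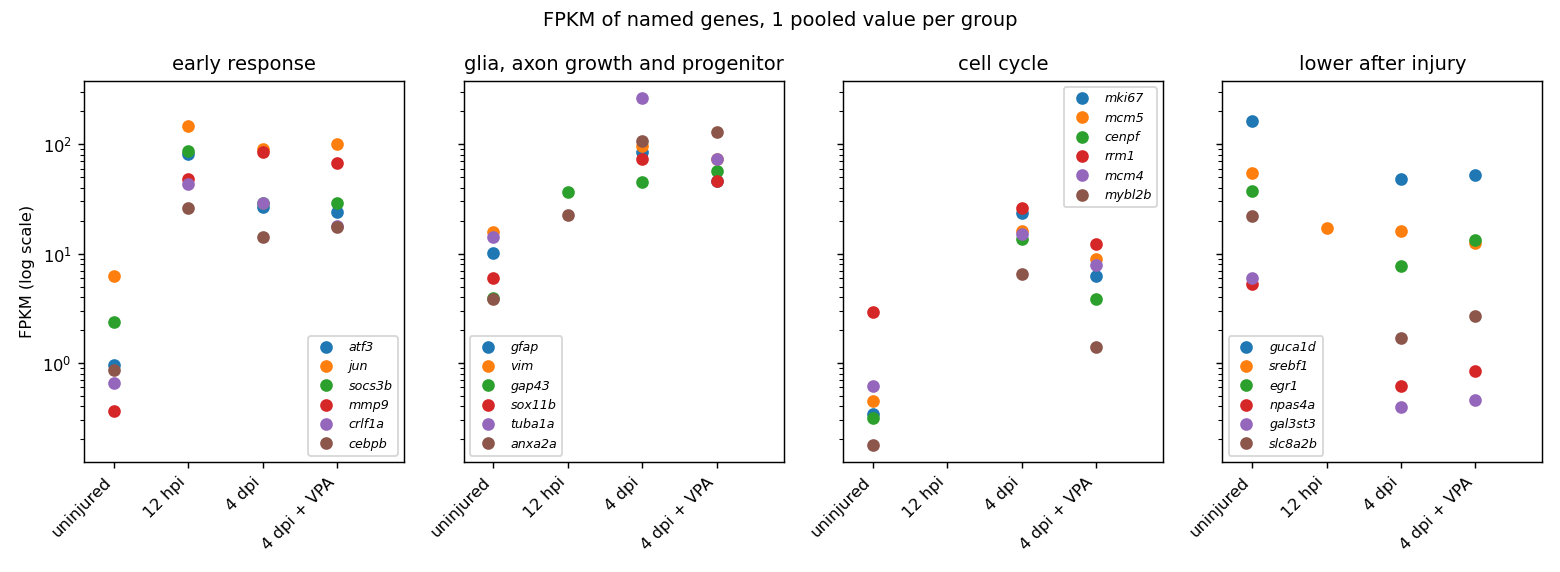
FPKM on a log axis for named genes in the 4 groups, with 1 pooled value of the authors per group and a point only where the gene was listed. The genes were chosen after their values were seen: *atf3* reached 81.8 FPKM at 12 hpi, and *mki67* stood at 23.6 FPKM at 4 dpi and 6.22 FPKM at 4 dpi + VPA.

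The next comparison asked which genes differed from uninjured retina at 4 dpi. Genes of the cell cycle, regeneration-associated factors, Müller glia genes and macrophage genes were listed higher, and clock and photoreceptor genes were mostly listed lower. Few photoreceptor genes were listed at all, 1 of 28 on the rod list, 3 of 42 on the cone list and 4 of 42 on the shared list. *mki67*, a marker of dividing cells, was at 0.339 FPKM in uninjured retina and 23.6 FPKM at 4 dpi, a log2 fold change of 6.12 (SE 0.97, p = 0.00025, q = 0.135) in the authors' deposited table, again a larger p than the SE would give. *sox11b*, a transcription factor of neural progenitors and regrowing neurons, rose from 6.0 to 74.1 FPKM, a log2 fold change of 3.63 (SE 0.84, p = 5e-05, q = 0.0421) in the authors' deposited table. *gfap*, an intermediate filament gene of reactive Müller glia, was at 10.2 and 84.6 FPKM, with a log2 fold change of 3.05 (SE 0.76, p = 1e-04, q = 0.0726) in the authors' deposited table. *mki67* lies on chromosome 12 from 10328773 to 10343439, *sox11b* on chromosome 20 from 30128698 to 30181234 and *gfap* on chromosome 3 from 31660726 to 31672767.

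All 37 listed cell cycle genes were higher at 4 dpi (median 3.69, percentile 100.0). The mitotic cyclin gene *ccnb1* was at 0.277 and 18.2 FPKM, the replication licensing gene *mcm2* at 0.323 and 16.2 FPKM, and *rrm2*, a subunit of ribonucleotide reductase, at 0.380 and 18.8 FPKM in the more abundant of its annotated loci. Among the highest fold changes outside the list were *aspm*, a spindle pole gene, at 0.149 and 9.82 FPKM, *kpna2*, a nuclear import gene, at 0.530 and 34.8 FPKM, and *kif4*, a chromosome-associated kinesin gene, at 0.138 and 6.96 FPKM. All 18 listed regeneration-associated factors were higher (median 3.18, percentile 100.0). They included the progenitor transcription factors *insm1a* at 2.83 and 35 FPKM, *olig2* at 0.671 and 15.5 FPKM, *atoh7* at 1.15 and 11.3 FPKM, *foxn4* at 0.453 and 4.87 FPKM, *zic2b* at 0.947 and 14.2 FPKM and *sox2* at 7.54 and 23.9 FPKM. The Notch pathway list had 7 genes higher and 0 lower (median 3.77, percentile 97.8, or 96.22 at a pseudocount of 1), with the Delta ligand genes *dla* at 0.269 and 6.51 FPKM, *dlb* at 0.181 and 6.45 FPKM and *dld* at 0.439 and 7.26 FPKM and the target gene *her4.2* at 0.286 and 7.62 FPKM.

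The Müller glia list had 9 members higher and 1 lower (median 2.73, percentile 99.5). The brain fatty acid binding protein gene *fabp7a* was at 52.0 and 1191 FPKM and the apolipoprotein gene *apoeb*, which macrophages also express, at 234 and 2111 FPKM. The ganglion cell list had 6 higher and 1 lower (median 3.51, percentile 99.6), with the alpha tubulin gene *tuba1a* at 14.2 and 263 FPKM and *gap43* at 3.89 and 45.5 FPKM. Outside the lists, the beta tubulin gene *tubb5* rose from 7.87 to 224 FPKM (log2 fold change 4.83, q = 0.0421) in the authors' deposited table. All 28 listed macrophage and microglia genes were higher (median 2.75, percentile 100.0), among them the complement gene *c1qc* at 1.69 and 28.4 FPKM and the chemokine receptor gene *cxcr4b* at 1.11 and 14.5 FPKM, and *lgals3bpb* rose from 13.9 to 151 FPKM (log2 fold change 3.44, q = 0.0421) in the authors' deposited table. The Müller glia and macrophage medians lay near 2.61, the median log2 fold change of all entries listed higher at 4 dpi, where finite. Their percentiles, drawn against genes of both directions, thus do not show larger changes than in other genes listed higher. The 5 listed neutrophil genes were higher (median 3.12, percentile 87.6), and *lect2l* rose from 0 to 4.32 FPKM. The inflammatory list had 10 higher and 0 lower (median 3.81, percentile 98.2). Its median was 1.87 (percentile 91.34) at a pseudocount of 1, 5.49 at 0.01 and 2.97 (percentile 96.99) without entries under 0.01 FPKM, and the complement gene *c3a.1* and the chemokine gene *ccl34a.4* rose from 0 to 1.23 and 14.6 FPKM. All 17 listed interferon response genes were higher (median 2.92, percentile 99.7), with the ubiquitin-like gene *isg15* at 5.49 and 88.5 FPKM and *ifit8* at 0.482 and 14.8 FPKM.

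All 24 listed extracellular matrix and adhesion genes were higher (median 2.54, percentile 94.9, or 97.91 at a pseudocount of 0.01). *anxa2a*, a membrane-binding annexin gene, rose from 3.85 to 108 FPKM (log2 fold change 4.81, q = 0.0421) in the authors' deposited table, and *mmp9* was at 0.363 and 85.7 FPKM and *mmp14b* at 0.869 and 21.7 FPKM. The immediate early and AP-1 list had 9 higher and 3 lower (median 2.46, percentile 79.0), and *jun*, an AP-1 subunit, rose from 6.21 to 90.9 FPKM (log2 fold change 3.87, q = 0.0421) in the authors' deposited table. The 4 listed heat shock genes were higher, among them *cryabb* at 1.11 and 17.3 FPKM, as were the 4 listed genes of apoptosis, including *casp3a* at 5.75 and 30.6 FPKM. The 3 listed genes of the Wnt, Hedgehog and TGF-beta pathways were higher, with the Hedgehog genes *gli2a* at 1.3 and 5.01 FPKM and *smo* at 1.13 and 4.78 FPKM. Of 85 ribosomal protein genes, 72 were listed and all were higher (median 2.22, percentile 99.2), such as *rps2* at 139 and 930.5 FPKM. The median log2 fold change of all entries listed higher, where finite, was 2.61. The percentile, drawn against genes of both directions, thus does not show larger changes than in other genes listed higher. The listed ribosomal protein genes spanned a median of 5.54 kb of the genome, less than the 10.1 kb of all genes listed higher, and a part of gene length or RNA quality in their difference was not tested. In the HDAC and histone modifier list 7 genes were higher and 4 lower (median 1.83, percentile 60.2). The histone variant gene *h2afx* on this list was at 6.31 and 135 FPKM. Of the deacetylase genes themselves, which were chosen here after their values were seen, *hdac1* was at 30.4 and 83.1 FPKM, *hdac5* at 50.0 and 15.3 FPKM and *hdac9b* at 171 and 39.4 FPKM.

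Among the genes lower at 4 dpi, *nfatc3a*, a calcineurin-regulated transcription factor gene, fell from 36.7 to 2.97 FPKM (log2 fold change -3.63, q = 0.0421) in the authors' deposited table. The sodium-calcium exchanger gene *slc8a2b* was at 22.2 and 1.70 FPKM, the synaptic vesicle gene *syn2b* at 29.0 and 2.62 FPKM, the transcription factor gene *sox6* at 30.5 and 2.84 FPKM, the nuclear receptor gene *esrrgb* at 64.8 and 6.21 FPKM and the sulfotransferase gene *gal3st3* at 6.04 and 0.398 FPKM. The clock list had 1 gene higher and 7 lower (median -2.04, percentile 0.7). The period genes *per2* and *per3* were at 111 and 15 FPKM and at 176 and 38.1 FPKM, *nr1d1* was at 55.0 and 10.2 FPKM, and *aanat2*, the enzyme gene of melatonin synthesis, was at 26.8 and 141 FPKM. Cholesterol and fatty acid genes were listed 4 higher and 4 lower (median 0.0359, percentile 19.1), with *fdft1* at 33.8 and 2.62 FPKM and the lipoprotein gene *apoc1* at 25.8 and 266 FPKM. The shared photoreceptor list had 4 lower, including *impdh1a* at 238 and 53 FPKM and *crb1* at 55.6 and 17.4 FPKM. The cone list had 1 higher and 2 lower, with the guanylate cyclase activator gene *guca1d* at 165 and 48.4 FPKM, and the rod list had *nr2e3* at 11.9 and 37.2 FPKM. The bipolar list had 1 higher and 2 lower, with the calcium-binding protein gene *cabp2a* at 183 and 35.3 FPKM, and *trpm1b* was the 1 listed pigment epithelium gene, at 48.3 and 13.2 FPKM.

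Members of the lens, cornea and skin list were listed at 4 dpi too. All 15 listed members of the lens, cornea and skin list were higher (median 5.52, percentile 100.0). The median was 2.68 at a pseudocount of 1, 8.80 at 0.01 and 3.26 (percentile 97.63) without entries under 0.01 FPKM, and *cryaa*, *crygm3* and the lens connexin gene *cx44.1* rose from 0 to 11.3, 39.3 and 4.46 FPKM. The red blood cell list had 2 higher, the globin gene *hbz* at 0 and 1.2 FPKM and *prdx2* at 43.4 and 155 FPKM. The endothelial list had the claudin genes *cldn5a* at 1.67 and 14.6 FPKM and *cldn5b* at 0.786 and 13.2 FPKM higher and *rgs5a* lower, at 23.3 and 7.80 FPKM. The oligodendrocyte and optic nerve list had 3 higher, among them the myelin genes *mbpb* at 10.3 and 43.7 FPKM and *mag* at 11.4 and 35.3 FPKM. The amacrine and horizontal cell, mitochondrially encoded and muscle lists had 0 listed members. Of the 45 genes marked significant, each at q = 0.0421 in the authors' deposited table, 32 were at 0 in uninjured retina, and the median q of all 4 dpi entries was 0.999. Among the 45 were 5 entries of the lens, cornea and skin list. Genes listed higher spanned a median of 10.1 kb of the genome and genes listed lower 47.4 kb.

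**Figure D2:**
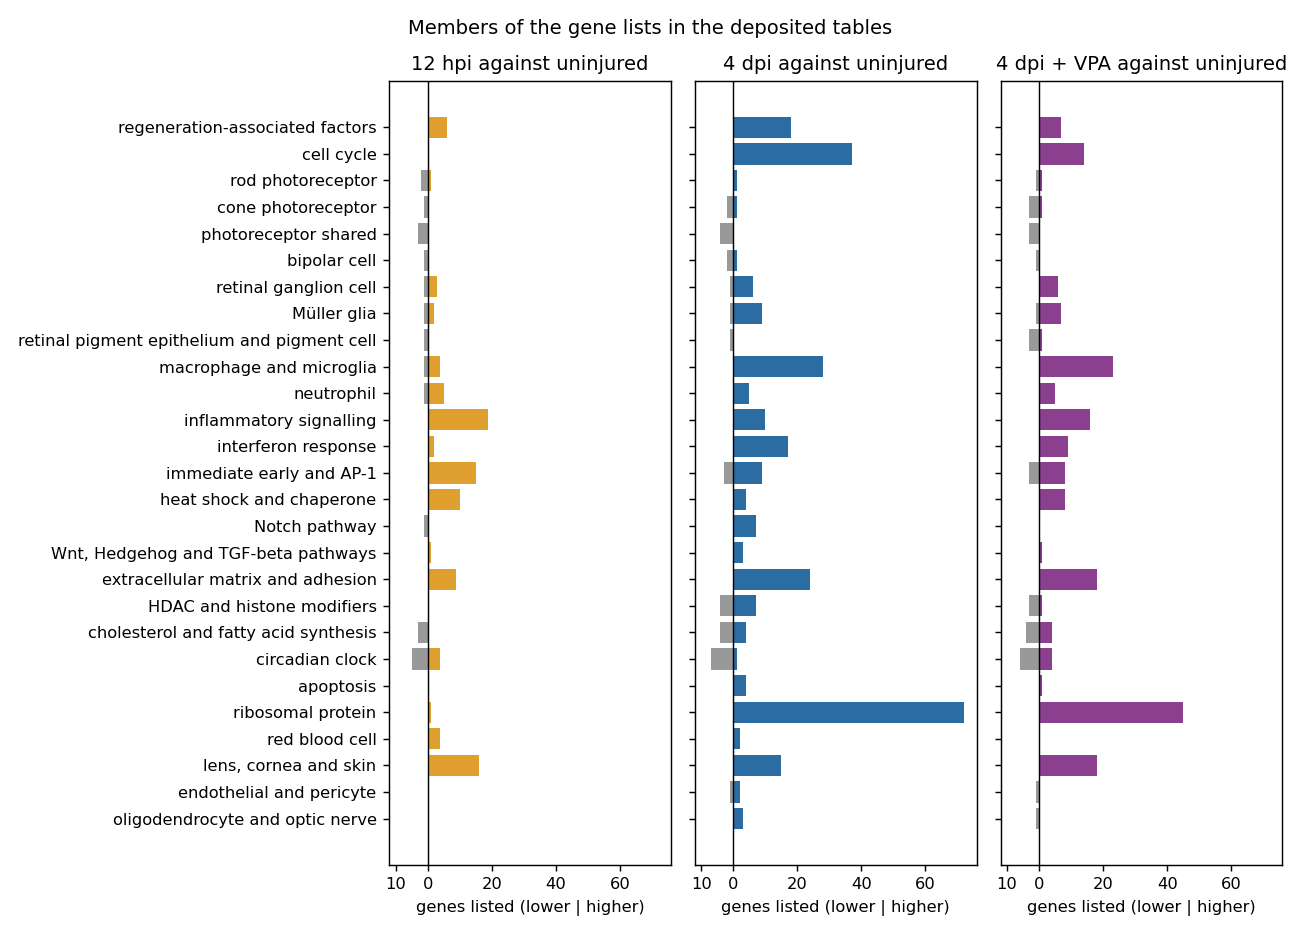
Number of members of each fixed gene list that the authors' deposited tables list higher (coloured bars) or lower (grey bars) than uninjured retina, with a panel for each comparison. At 4 dpi the bars show 37 cell cycle genes, 72 ribosomal protein genes and 28 macrophage and microglia genes higher and 0 lower.

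The third comparison set retinae at 4 dpi from fish kept in VPA beside uninjured retina. Macrophage, inflammatory, Müller glia and ganglion cell genes were listed higher, along with 14 cell cycle genes. *anxa2a* was at 3.85 FPKM in uninjured retina and 129 FPKM at 4 dpi + VPA, with a log2 fold change of 5.07 (SE 0.88, p = 5e-05, q = 0.0717) in the authors' deposited table. *jun* was at 6.21 and 101 FPKM, with a log2 fold change of 4.02 (p = 5e-05, q = 0.0717) in the authors' deposited table. *gap43* was at 3.89 and 57.1 FPKM, and *mki67* at 0.339 and 6.22 FPKM (p = 0.00245, q = 0.938) in the authors' deposited table. *anxa2a* lies on chromosome 25 from 33527665 to 33541952.

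All 23 listed macrophage and microglia genes were higher at 4 dpi + VPA (median 2.99, percentile 100.0), with *apoc1* at 17.2 and 421 FPKM in its more abundant transcript and *rac2* at 0.698 and 17 FPKM. All 16 listed inflammatory genes were higher (median 3.81, or 2.51 at a pseudocount of 1, percentile 100.0 and 99.96), and the chemokine genes *ccl34a.4* and *cxcl8b.1* were listed at 0 in uninjured retina and at 31.1 and 4.36 FPKM. The 5 listed neutrophil genes were higher (median 4.08, percentile 91.4), with a median of 2.47 (percentile 99.08) at a pseudocount of 1 and 7.32 at 0.01, with *lect2l* at 0 and 9.0 FPKM, and so were the 9 listed interferon genes (median 2.52, percentile 88.8), with *isg15* at 5.49 and 66.0 FPKM. The Müller glia list had 7 higher and 1 lower (median 2.63, percentile 99.8). The listed transcript of *fabp7a* was at 25 and 479 FPKM and the calcium-binding protein gene *icn* at 42.3 and 347 FPKM. The 6 listed ganglion cell genes were higher (median 2.64, percentile 98.6), with *sox11b* at 6.0 and 46.1 FPKM and *tuba1a* at 14.2 and 73.8 FPKM. The Müller glia and ganglion cell medians lay near 2.54, the median log2 fold change of all entries listed higher at 4 dpi + VPA, where finite. Their percentiles, drawn against genes of both directions, thus do not show larger changes than in other genes listed higher. At 4 dpi and at 4 dpi + VPA the ganglion cell genes listed higher were the same 6, *atf3*, *gap43*, *klf6a*, *sox11b*, *tuba1a* and *tuba1b*, of which *atf3* and *klf6a* are also on the immediate early list and *sox11b* on the regeneration list, while *robo2*, another member, was lower at 4 dpi. Of these genes *klf6a*, *tuba1b* and *robo2* are named here after their values were seen, to give the members in full. The number of ganglion cells cannot be read from these genes. The immediate early list had 8 higher and 3 lower (median 2.19, percentile 90.9), with *atf3* at 0.952 and 24.2 FPKM and *cebpb* at 0.861 and 17.4 FPKM.

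Of the regeneration-associated factors 7 were listed, all higher (median 2.92, percentile 95.1, or between 98.64 and 99.27 under 3 alternatives): *crlf1a* at 0.659 and 18 FPKM, *mycb* at 5.25 and 23.2 FPKM, *mych* at 0.579 and 17.3 FPKM, *hbegfa* at 0.621 and 4.97 FPKM, *socs3b* at 2.39 and 28.9 FPKM, *ttk*, a mitotic kinase gene, at 0.306 and 2.68 FPKM, and *sox11b*. The cell cycle list had 14 higher and 0 lower (median 2.90, percentile 63.1, with a median of 1.83 at a pseudocount of 1 and a percentile of 98.06 without entries under 0.01 FPKM), with the replication licensing genes *mcm5* at 0.448 and 8.93 FPKM and *mcm4* at 0.568 and 7.90 FPKM and the cytokinesis gene *anln* at 0.171 and 3.47 FPKM. The Notch list had 0 listed members. Of its 7 genes higher at 4 dpi, 2 have 1 annotated transcript, and for the others the change from gene to transcript level cannot be told apart from a difference. The 18 listed extracellular matrix genes were higher (median 2.58, percentile 96.5, or between 97.66 and 99.54 under 5 alternatives), with *mmp9* at 0.363 and 67.8 FPKM and the fibronectin gene *fn1a* at 0.628 and 12 FPKM. All 8 listed heat shock and chaperone genes were higher (median 2.62, percentile 95.2), with *cryabb* at 0.688 and 29.4 FPKM and the calreticulin gene *calr3b* at 4.09 and 36.6 FPKM. Ribosomal protein genes were listed 45 higher and 0 lower (median 1.77, percentile 94.7), with *rps12* at 95.6 and 446 FPKM. The HDAC and histone modifier list had *h2afx* higher, at 6.31 and 35.8 FPKM, and 3 lower, *hdac9b* at 101.5 and 25.9 FPKM, the acetyltransferase genes *kat6a* at 16.5 and 5.39 FPKM and *crebbpa* at 6.89 and 1.57 FPKM. The apoptosis list had *fas* higher, at 1.05 and 9.06 FPKM, and the Wnt, Hedgehog and TGF-beta list a transcript of *tcf7l2*.

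The clock list had 4 genes higher and 6 lower at 4 dpi + VPA (median -1.60, percentile 14.6), with *per2* at 52.1 and 5.38 FPKM and *nr1d4b* at 1.45 and 10.2 FPKM. The cholesterol and fatty acid list was divided into 4 higher and 4 lower (median -0.137, percentile 18.5, or -2.10 and 1.67 without entries under 0.01 FPKM), with *fdft1* at 26.6 and 3.31 FPKM and the cholesterol exporter gene *abca1b* at 0.643 and 6.23 FPKM. The pigment epithelium list had 1 higher, the melanosome gene *pmelb* at 18.7 and 58.2 FPKM, and 3 lower, among them the retinol dehydrogenase gene *rdh5* at 28.8 and 3.43 FPKM and the channel gene *best1* at 6.0 and 1.21 FPKM. The cone list had 1 higher and 3 lower, with the opsin kinase gene *grk7b* at 11.4 and 1.75 FPKM, and the shared photoreceptor list had 3 lower, with *impdh1a* at 150.2 and 41.4 FPKM. The rod list had *nr2e3* higher, at 11.9 and 43.6 FPKM, and *rcvrna* lower, at 237 and 85.7 FPKM. *trpm1b* was the 1 listed bipolar gene, at 36.0 and 9.77 FPKM, *rgs5a* the 1 listed endothelial gene, at 14.7 and 2.17 FPKM, and the myelin gene *mbpa* the 1 listed oligodendrocyte gene, at 36.3 and 5.89 FPKM. Also among the lowest fold changes were *cyp19a1b*, the brain aromatase gene, at 6.36 and 0.647 FPKM, *gal3st3* at 6.04 and 0.458 FPKM and *slc8a2b* at 22.2 and 2.67 FPKM.

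All 18 listed members of the lens, cornea and skin list were higher at 4 dpi + VPA (median 6.76, percentile 100.0), with a median of 4.31 at a pseudocount of 1, 9.03 at 0.01 and 4.49 without entries under 0.01 FPKM, and with *crygm3* and *crygs4* at 0 in uninjured retina and at 304 and 161 FPKM. *fabp11a*, which is on the Müller glia list, was at 1.54 and 792 FPKM. The red blood cell, amacrine and horizontal cell, mitochondrially encoded and muscle lists had 0 listed members. At 4 dpi + VPA the lowest q was 0.0717, shared by 41 transcripts at p = 5e-05, with a median q of 0.997 in the authors' deposited table. As at 12 hpi, 0 transcripts were marked significant at this p, which the gene-level 4 dpi tables marked, so the absence of marks is no sign of an effect of VPA. Of the 41 transcripts at the lowest q, 11 were of the lens, cornea and skin list.

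Genes listed in more than 1 comparison were mostly listed in the same direction. Between 4 dpi + VPA and 4 dpi, 414 genes were higher in both and 300 lower in both, 99.86% of those shared, with *cdc25b*, a mitotic phosphatase gene, as the exception. Between 12 hpi and 4 dpi, 119 genes were higher in both and 64 lower in both (97.86%), and between 12 hpi and 4 dpi + VPA the numbers were 175 and 82 (99.23%). *atf3*, *socs3b*, *cebpb*, *mmp9*, *crlf1a*, *hbegfa*, *gap43* and *nr2e3* were higher in all 3 comparisons. The uninjured control was shared, and unchanged groups simulated against it gave the same sign for 99.88% of the entries listed in both and an overlap of 18.9%. Counted by table entries and not by gene names, the observed overlaps were 69.2% of the 4 dpi + VPA transcripts at 4 dpi, 30.9% of the 12 hpi transcripts at 4 dpi and 41.5% of the 12 hpi transcripts at 4 dpi + VPA. By gene name, 69.6% of the higher and 68.3% of the lower genes at 4 dpi + VPA were listed in the same direction at 4 dpi, 31.2% and 30% of those at 12 hpi at 4 dpi, and 45.9% and 38.5% of those at 12 hpi at 4 dpi + VPA. In the order of the overlaps, the covariance of the log2 fold changes was 7.68, 8.92 and 8.50 over the 476, 103 and 192 shared entries with an FPKM of at least 0.1 in every group and an uninjured FPKM equal within 10%, against simulated values of 5.11, 5.25 and 5.29. The simulated values include the shared control but hold no effects. The simulation took the scores as normal, while the authors' p-values were larger than those of a normal distribution. The covariance also rests on standard errors that understate the uncertainty of genes with large changes. The simulated covariances may therefore be too low. With 1 control sample the control could not be split, and part of the excess of the overlaps may come from sharing it between groups with effects.

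The effect of VPA on injured retina was not compared by the authors' tables directly, so 4 dpi + VPA was set beside 4 dpi for genes listed in both. Cell cycle genes were mostly lower with VPA, and crystallin genes were higher. *mki67* was at 23.6 FPKM at 4 dpi and 6.22 FPKM at 4 dpi + VPA (log2 ratio -1.90), the kinetochore gene *cenpf* was at 13.7 and 3.88 FPKM (-1.79), *dlgap5*, a spindle gene, at 8.43 and 2.26 FPKM (-1.86) and *mybl2b*, a transcription factor of the cell cycle, at 6.52 and 1.41 FPKM (-2.13). Counted by gene identifier rather than by name, 725 genes were listed in both, of which 549 had an uninjured FPKM equal within 10% in both tables, and over these the median log2 ratio was -0.0834 (quartiles -0.495 and 0.245). The median was -0.223 for genes higher at 4 dpi and 0 for genes lower at 4 dpi.

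Of 9 cell cycle genes, 8 were lower with VPA (median -1.10, percentile 0), and the median was -1.32 over the 4 with 1 annotated transcript. *tuba1a* was at 263 FPKM at 4 dpi and 73.8 FPKM at 4 dpi + VPA, *tubb5* at 224 and 63.2 FPKM, the kinesin gene *kif4* at 6.96 and 2.17 FPKM, and the histone genes *h2afx* and *hist2h3c* at 135 and 35.8 FPKM and at 168 and 47.8 FPKM. All 6 genes with histone names, a set chosen after their values were seen, were lower, with log2 ratios from -4.06 to -1.81 (median -2.11). Of 35 ribosomal protein genes 34 were lower (median -0.612, percentile 35.7). Their median lay below the lower quartile of -0.495 over all 549 genes. The random lists came from bins of similar expression that held the ribosomal protein genes themselves, so this percentile does not show that their median was ordinary. The medians were -0.581 for 5 ganglion cell genes (percentile 20.4), -0.372 for 5 Müller glia genes (percentile 61.6) and -0.223 for 8 extracellular matrix genes (percentile 18.9). The medians of 16 macrophage and microglia genes (0.0799, percentile 89.1), 8 inflammatory genes (0.246, percentile 92.1) and 8 immediate early genes (0.188, percentile 90.5) lay above 0 and inside the limits. Of 4 interferon response genes, all with 1 annotated transcript, 3 were lower (median -0.613), too few for a percentile. Among the regeneration-associated factors, *sox11b* was at 74.1 FPKM at 4 dpi and 46.1 FPKM at 4 dpi + VPA, *crlf1a* at 29.3 and 18 FPKM, *hbegfa* at 4.23 and 4.97 FPKM and *socs3b* at 28.8 and 28.9 FPKM.

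Of 15 lens, cornea and skin genes 14 were higher with VPA (median 1.69, percentile 100.0), including *crygm3* at 39.3 FPKM at 4 dpi and 304 FPKM at 4 dpi + VPA and *cryaa* at 11.3 and 41.8 FPKM. *fabp11a* was at 135 and 792 FPKM, and the peptide YY gene *pyya* at 8.62 and 24.6 FPKM. The log2 ratio of *fabp11a*, 2.55, lay apart from those of the other Müller glia genes with a ratio, which ran from -0.87 (*gfap*) to 0.19 (*icn*). It thus does not stand for that list. Of 408 gene identifiers with 1 annotated transcript that were higher at 4 dpi, 214 (52.5%) were also listed higher at 4 dpi + VPA, among them 9 of 11 macrophage and microglia genes, 13 of 17 ribosomal protein genes and 4 of 8 cell cycle genes. Of the regeneration-associated factors higher at 4 dpi, with any number of annotated transcripts, 6 of 18 were also listed higher at 4 dpi + VPA. Among the 6 with 1 annotated transcript this held for 1, *sox11b*, and *atoh7*, *hmgb2b*, *olig2* and *sox2* were among those not listed at 4 dpi + VPA. None of these differences between 4 dpi + VPA and 4 dpi was tested, and genes listed in only 1 of the comparisons do not enter the ratios.

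**Figure D3:**
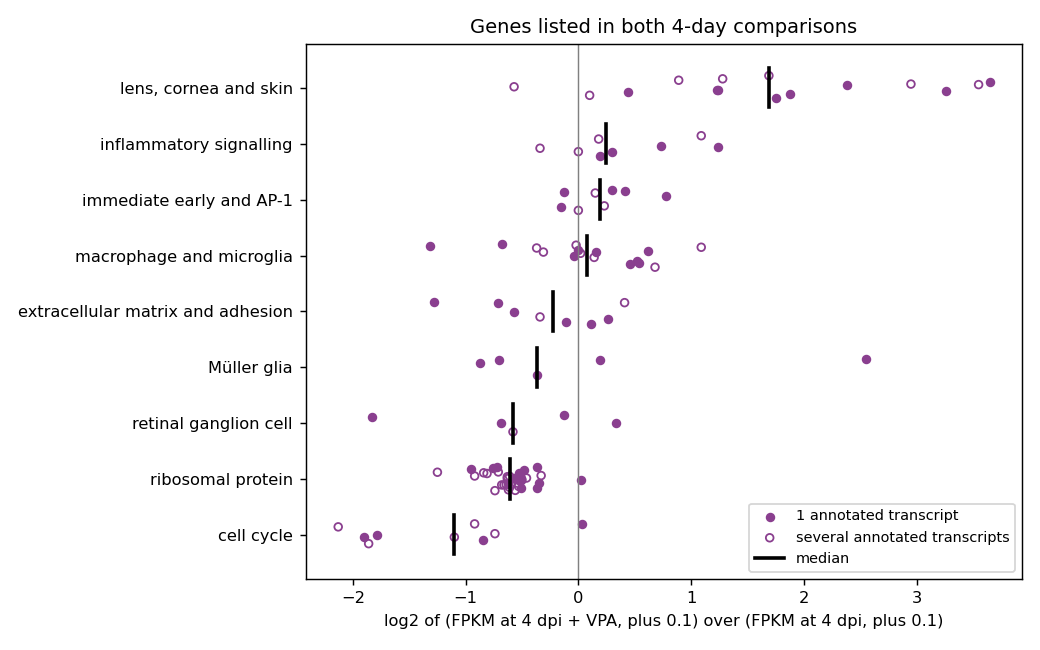
Log2 ratio of FPKM at 4 dpi + VPA to 4 dpi for genes listed in both comparisons, by gene list; each point is a gene, filled where it has 1 annotated transcript and open where it has several, and black bars are medians. The cell cycle median lies at -1.10 and the lens, cornea and skin median at 1.69.

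**Figure D4:**
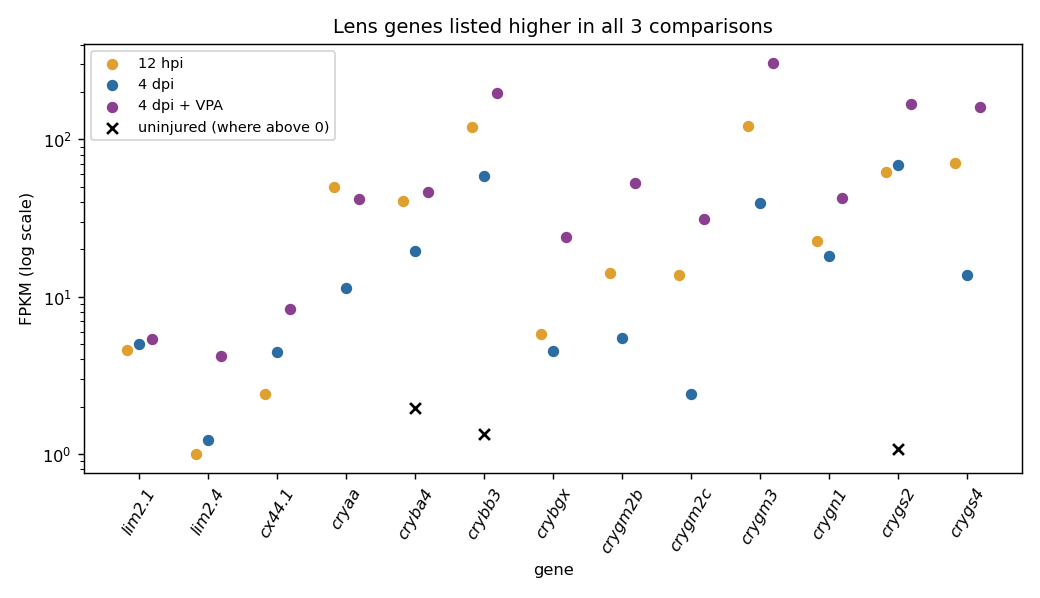
FPKM on a log axis of 13 lens genes listed higher in all 3 comparisons, with 1 pooled value of the authors per injured group and crosses for uninjured retina where it was above 0. All 13 were higher at 4 dpi + VPA than at 4 dpi, and 10 were at 0 in uninjured retina.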

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

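All tests in this part were chosen after the results were seen. Several genes were listed in opposite directions in a pair of comparisons against the same uninjured retina, and none of these differences was tested. The phosphatase gene *cdc25b* had a log2 fold change of -12.57 at 4 dpi + VPA and 2.39 at 4 dpi in the authors' deposited tables. *mhc2dab*, an antigen presentation gene, was at -14.02 at 12 hpi and 2.56 at 4 dpi, and the peroxiredoxin gene *prdx1* at -13.22 and 2.80 in the authors' deposited tables. In these 3 genes, which have between 2 and 4 annotated transcripts, the lower value belongs to a transcript close to 0 FPKM and the higher value to the whole gene. *CABZ01111555.1*, with 1 annotated transcript, was at 2.29 at 12 hpi, -1.92 at 4 dpi and -2.31 at 4 dpi + VPA, and *agrp2*, an agouti-related peptide gene with 1 annotated transcript, at 1.46 at 12 hpi and -2.33 at 4 dpi + VPA in the authors' deposited tables.

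Lens transcripts at 0 FPKM in uninjured retina and present in all 3 injured groups were weighed between lens tissue carried over at dissection and crystallin expression by retinal cells. Of the 14 lens genes in the fixed list that are not crystallins, 3 were listed higher in all 3 comparisons, the membrane protein genes *lim2.1* and *lim2.4* and the connexin gene *cx44.1*, all at 0 FPKM in uninjured retina, which is what lens tissue carried over into the injured samples would give, with the limit of 3 genes set after the values were seen. These 3 genes did not follow the crystallins between 12 hpi and 4 dpi. They were higher at 4 dpi (*lim2.1* 4.59 and 4.98 FPKM, *lim2.4* 1.005 and 1.23, *cx44.1* 2.39 and 4.46). Every one of the 10 crystallins but *crygs2* was lower at 4 dpi, such as *cryaa* at 50.0 and 11.3 FPKM. The 3 genes have several annotated transcripts, so the level of the tables may play a part. The lens transcription factor gene *pitx3*, singled out after its values were seen, was at 0 in uninjured retina and at 1.12, 1.84 and 3.28 FPKM at 12 hpi, 4 dpi and 4 dpi + VPA. Crystallin expression by retinal cells after injury would also raise crystallins, of which 10 of 49 were listed higher in all 3 comparisons, so that both sources may contribute and cannot be told apart for these 10 genes, since no dissection record or count of lens cells was used here. The amount of lens RNA, the injury and VPA go together in the design, and an effect of VPA on crystallin genes stays open and untested.

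Cell cycle genes were lower at 4 dpi + VPA than at 4 dpi among genes listed in both, and the gene-level values at 4 dpi were set against transcript-level values at 4 dpi + VPA. For cell cycle genes with 1 annotated transcript that difference in level cannot arise, and their median log2 ratio was -1.32, with 3 of 4 genes lower and *dhfr* as the exception at 0.03, by a limit on the median that was set after the values were seen and that replaced a stricter one asking for every gene to be lower, which *dhfr* had left undecided. For the 5 cell cycle genes with several annotated transcripts the median was -1.10, where the level of the tables and a real difference cannot be told apart. A response weaker by the same amount in all injury-responsive genes in 4 dpi + VPA is argued against by the inflammatory genes. Of the 10 higher at 4 dpi, 8 had a ratio, and with the other 2 placed lowest the median was still at least 0.177 and the lower quartile at least -0.336, above the cell cycle median. The inflammatory list was chosen after the values of all lists were seen. Of the 17 interferon response genes higher at 4 dpi, 4 had a ratio and 3 of these were lower (median -0.613). The median over all 17 has no bound, and the inflammatory genes do not stand for all immune genes. The 16 macrophage and microglia genes with a ratio had a median of 0.0799, but 28 were higher at 4 dpi, and with the other 12 placed lowest the median is only known to be at least -0.677 and the lower quartile has no bound, so they decide nothing. Of 35 ribosomal protein genes with a ratio 34 were lower (median -0.612), and the median of all genes higher at 4 dpi was -0.223, so a weaker response of part of the injury-responsive genes and an effect on dividing cells cannot be told apart for the ribosomal protein genes, because both would lower them and no ratio was tested. An effect of VPA on dividing cells, a difference between the fish of each group, or another time course of proliferation may each remain, and none was tested.

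Clock genes were listed in both directions, and the retinae may have been taken at another time of day. That explanation predicts that activating-arm clock genes move against the *per*, *cry* and *nr1d* genes in each comparison, but 0 activating-arm clock genes were listed at 4 dpi, and 4 were lower at 12 hpi, where *nr1d4a* and *nr1d4b* were higher but a transcript of *nr1d2a* was lower, in the direction of the activating arm. At 4 dpi + VPA 0 activating-arm genes were listed, with 2 genes of the other arm higher and 6 lower. Collection times were not used here, so time of day and injury cannot be told apart for these genes.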

How the results depend on the processing

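The settings of an FPKM of at least 0.01 in both groups, a q below 0.1, genes with 1 annotated transcript, matching of list members through gene identifiers and a pseudocount of 1 for named genes were chosen after seeing the data. At a q below 0.01 every count of genes listed higher or lower was 0, as were both overlaps, which had to be so since the lowest q was 0.0421 or 0.0717, and this setting shows nothing about the results. At a q below 0.1 there were 24 genes higher and 0 lower at 12 hpi, 55 and 5 at 4 dpi, and 37 and 1 at 4 dpi + VPA. With a fold change of at least 4, the genes listed lower numbered 133 at 12 hpi, 269 at 4 dpi and 232 at 4 dpi + VPA. Among genes with 1 annotated transcript, 200 were higher and 83 lower at 12 hpi, 385 and 223 at 4 dpi, and 279 and 199 at 4 dpi + VPA, and 356 were shared in direction between 4 dpi + VPA and 4 dpi and 93 between 12 hpi and 4 dpi. With an FPKM of at least 0.01 in both groups 245 genes were higher at 12 hpi. These counts fell because each setting keeps fewer entries. Of the list medians, 6, 11 and 5 lay outside the limits at 12 hpi, 4 dpi and 4 dpi + VPA. With an FPKM of at least 0.01 in both groups there were 3 at 12 hpi and 9 at 4 dpi + VPA, and at a pseudocount of 1 there were 8 at 4 dpi + VPA; the cause was not tested. Over all settings 295 list medians kept their direction and their side of the limits or, for 4 dpi + VPA over 4 dpi, stayed within 0.1 of their value, 13 moved, 5 passed inside the limits, 12 passed outside them, and none that had been outside changed sign. The setting of an FPKM of at least 1 in a group could change none of them, because every listed entry already had an FPKM above 1 in the higher group. The 295 thus include medians that could not move, and that setting shows nothing about the results. The cholesterol median at 4 dpi, inside the limits, was -0.0406 at a pseudocount of 1. A pseudocount of 1 moved the log2 fold changes of 44 named genes by more than the error implied by the authors' test statistic, and 188 by less. Leaving out each replicate was not run because no value per replicate was used here. No paired analysis was possible because each group has 1 sample. Depth per library is unknown, so the lowest detectable level could not be given.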

Other observations

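The tests and the genes named in this part were chosen after the results were seen. Gene Ontology terms given in the deposited tables were counted for the listed genes, and the terms named were picked from those with at least 9 listed genes, all in 1 direction. There was no background of tested genes, so these are counts and not enrichments. All 9 listed genes of voltage-gated potassium channel activity were lower at 4 dpi, including *kcnd3* at 27.0 FPKM in uninjured retina and 5.02 FPKM at 4 dpi. The 10 listed genes of sodium ion transmembrane transport were lower as well, among them the sodium channel gene *scn8ab* at 13 and 3.48 FPKM and the vesicular glutamate transporter gene *slc17a7a* at 107 and 35.9 FPKM.

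Lysosome genes were listed 10 higher and 0 lower at 4 dpi, with the cathepsin genes *ctsk* at 0.642 and 28.4 FPKM, *ctsla* at 41.0 and 190 FPKM and *ctsd* at 57.1 and 197 FPKM, and 9 higher and 0 lower at 4 dpi + VPA, with *ctsk* at 0.642 and 11.7 FPKM. Genes of microtubule-based movement were 9 higher and 0 lower at 4 dpi, such as the spindle kinesin gene *kif11* at 0.452 and 14.9 FPKM. Nucleosome genes were 16 higher and collagen trimer genes 10 higher at 4 dpi, with 0 lower in each. Protein folding genes were 11 higher at 4 dpi and 12 higher at 4 dpi + VPA, including the chaperonin gene *cct3* at 34.5 and 103 FPKM and at 32.4 and 96.2 FPKM. Genes annotated to the immune response were 15 higher and 0 lower at 4 dpi + VPA.

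The level of 13 lens genes listed in all 3 comparisons was also set side by side between the injured groups. Their median log2 ratio was 1.04 for 12 hpi over 4 dpi (SD 1.1 across genes, from -0.901 to 2.51, with 9 of 13 higher at 12 hpi), 1.77 for 4 dpi + VPA over 4 dpi (SD 1.1) and 1.2 for 4 dpi + VPA over 12 hpi (SD 0.751, 12 of 13 higher), and all 13 were higher at 4 dpi + VPA than at 4 dpi. The genes not higher at 12 hpi than at 4 dpi were *lim2.1*, *lim2.4* and *cx44.1*, which are not crystallins, and the crystallin gene *crygs2*. The median of 1.04 was taken over all 13 genes, these included, and is not the median of the other crystallins alone. Genes listed lower spanned more of the genome than genes listed higher in each comparison, with medians of 30.5 and 9.98 kb at 12 hpi and 35.2 and 10.7 kb at 4 dpi + VPA.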
